A study of Triticum aestivum with 3 samples.

How the data were processed

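CUT&Tag was performed on protoplasts of bread wheat (Triticum aestivum) that had been transformed with PEG, and 3 libraries were deposited as peak lists. CUT&Tag directs a transposase to chromatin through an antibody and sequences the tagged fragments. Per the labels, an anti-GFP antibody or control IgG was used, and the aim was to find potential targets of TaSPL6-D, a member of the SBP-box family of plant transcription factors. There were 2 CUT&Tag replicates and 1 mock library. The labels call the mock both mock and input and do not say which antibody or construct it received. Nothing in the labels says that the replicates came from separate protoplast preparations, so the spread between them may be technical.

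The submitters' processing notes name bcl2fastq 2.17, Trimmomatic 0.39 and MACS2 2.2.7.1. The aligner, the genome build and the calling options are not given in the sources used here. The authors deposited 1 narrowPeak list per library, so peaks were called per sample and not on pooled reads. The deposited fold enrichment of each peak is a linear ratio of the fragments at its summit plus 1 to the local background plus 1, as the solution described next shows. It therefore understates enrichment most where the local background is low. The deposited −log10 p and −log10 q of each peak come from the authors' peak caller, and the lowest −log10 q was 1.31 in each list, which is a q of 0.05. The deposited score is 10 times the −log10 q, rounded down, for 99.97%, 99.99% and 100% of the peaks of replicate 1, replicate 2 and the mock, and it was not used further. These values are the authors' and were used to describe, rank or filter peaks within a list.

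The files hold no reads, and depth was recovered from the deposited values. The fold and the −log10 p of a peak together fix a whole number of fragments at the summit and a background level, under the formulas of MACS2. A whole number solved 99.98% of replicate 1 peaks, 99.99% of replicate 2 peaks and 100% of mock peaks within a relative tolerance of 1e-04. On 1979 simulated peaks the method returned the right number for 100%. The background rises in steps of 1 fragment per 10000 bp. From the steps and the lowest background, the genome carried 41.2 fragments per 10000 bp in replicate 1, 29.6 in replicate 2 and 18.5 in the mock. Fragments are not counted with molecular identifiers. Every interval given below was computed over peaks or regions taken as independent, although some lie in clusters. Peaks and regions are not replicates, so the intervals do not cover the spread between libraries.

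Peaks overlapping by at least 1 bp were taken as the same site. Shared regions were made by merging overlapping peaks of both replicates, and mock-free regions are those without a mock peak. Overlaps were set against 1000 random placements of the peaks on the same chromosomes with their widths kept. The permutation p is two-sided about the random mean, and the smallest it can take is 0.000999. Shares carry Wilson intervals at a confidence level of 95%, and subgenome shares were tested against 10000 multinomial draws. Fisher's exact tests were two-sided. These tests describe the 3 libraries, since no condition other than TaSPL6-D CUT&Tag had a replicate. The overlap code was tested on simulated lists of 4000 peaks with planted shares and returned them exactly.

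Gene positions and names came from a RefSeq gene table of the wheat assembly IWGSC CS RefSeq v2.1, with 102009 protein-coding genes on the 21 chromosomes. The lists name no build, so the join was tested on the values. Summits lay within 500 bp of a protein-coding gene edge for 18.6% of the placed replicate 1 peaks. This fell to 7.41% when all summits were moved by 2000 bp and to 1.63% when they were moved by 1000000 bp. The share without a move was the highest on 21 of 21 chromosomes in both replicates. Peak coordinates are given as in the deposited lists, counted from 1. Unplaced sequence, which held 20.1%, 22.5% and 44.5% of the peaks of replicate 1, replicate 2 and the mock, was left out of every step that uses genes or chromosomes.

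The table gives no strand, no product names and no sequence. The planned promoter share was therefore replaced by the share of summits in a gene body or within 2000 bp of either edge, and a target gene is a protein-coding gene with such a summit. The planned test for the GTAC core and the 15 planned gene lists were not run. The rule for named genes was to take the 20 target genes with the highest mean percentile rank of fold over both replicates among genes with a product name, and the 5 top regions. Without product names it was applied to all target genes, of which the text gives the leading ones, and target genes for which the table gives a common name were added after their values were seen. Genes of the HKT family and TaSPL6 itself carry no common name in the table and are not analysed here.

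To ask what depth alone would give, each peak's fragments and background were thinned to the depth of another library. The chance that the thinned peak would pass that library's lowest −log10 p was then computed. This chance differed from direct draws by at most 0.0046 in 4 simulated settings. For tRNA genes, 28 anticodons known from plant plastid genomes were listed from general knowledge after regions near tRNA genes had been seen. Alternatives chosen before the data were examined were a stricter q, a fold of at least 5, overlap of 50% of both peaks, summits within 100 bp, lists of equal length, each replicate alone, other treatments of mock peaks, displacement by 10 to 100 kb, the 21 chromosomes only and flanks of 1000 or 3000 bp. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.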

Results

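The data comprise 3 peak lists from wheat protoplasts, made to locate chromatin bound by TaSPL6-D. Replicate 1 held 12848 peaks, replicate 2 held 8401 and the mock held 1754. Median peak widths were 255, 264 and 280.5 bp. The median peak of each replicate had 12 fragments at its summit, and that of the mock had 16, so most calls rest on few fragments. The median deposited fold enrichment was 6.08, 6.34 and 7.89. The lowest background was 0.643, 0.49 and 0.36, so adding 1 lowers the folds of the lists by unlike amounts. Depth differed: relative to replicate 1, replicate 2 had 0.718 and the mock 0.449 of the fragments per unit of genome.

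The first comparison asked whether both replicates found the same places. Of the replicate 2 peaks, 7540 of 8401 lay at a replicate 1 peak (89.8%, Wilson 95% interval 89.1 to 90.4%). Of the deeper replicate 1, 58.0% of peaks lay at a replicate 2 peak. Random placement of the replicate 2 peaks gave a mean of 0.152% (permutation p = 0.000999, the smallest possible). Tall peaks recurred more often. Among replicate 1 peaks with 8 or fewer fragments 29.7% were found in replicate 2, and among those with 50 or more 95.6% were. Where such tall peaks were found in both, the median ratio of their fragments was 0.71 (bootstrap 95% interval 0.703 to 0.717), beside a ratio of depths of 0.718.

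**Figure D1:**
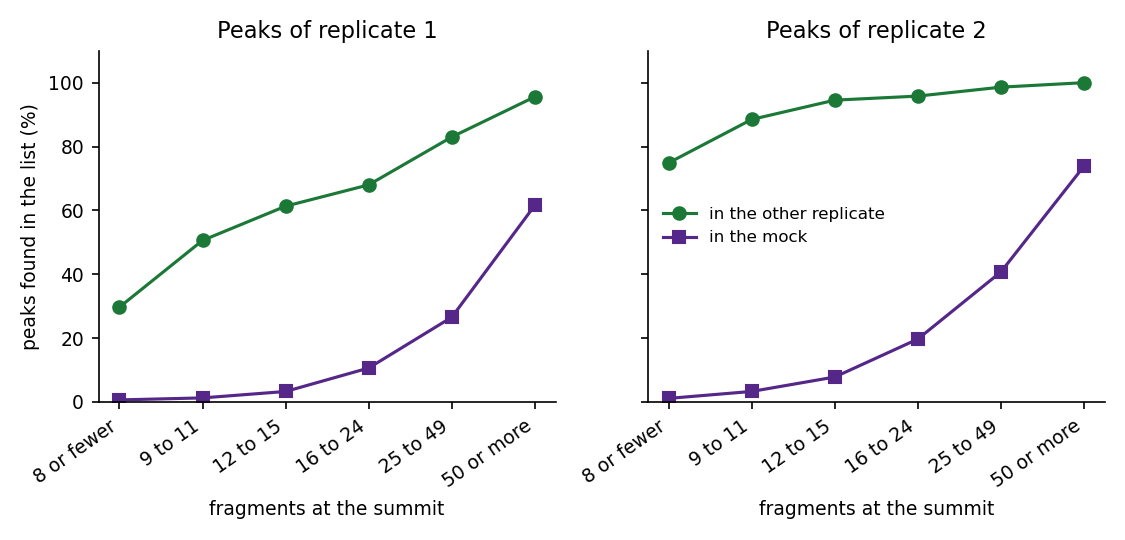
Share of peaks found in the other replicate (circles) and in the mock (squares), in %, by the number of fragments at the peak summit, for replicate 1 (left) and replicate 2 (right). Found shares rise with height in both panels, from 29.7 to 95.6% for replicate 1 in replicate 2 and from 0.62 to 61.6% for replicate 1 in the mock.

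The second comparison asked how many of the recurrent places were also called in the mock. Merging gave 7403 shared regions, of which 1446 held a mock peak (19.5%, Wilson 18.6 to 20.5%). The regions with a mock peak were the tall ones: their median was 56 fragments in replicate 1, against 13 in the 5957 mock-free regions. Median widths were 474.5 and 314 bp. Peaks seen in replicate 1 alone held a mock peak in 73 of 5390 cases (1.35%), and peaks seen in replicate 2 alone in 7 of 861 (0.813%). The odds were 17.7 and 29.6 times higher for shared regions (Fisher's exact test, p = 7.07e-271 and 1.14e-64). These odds set merged regions against single peaks without matching for height, so they do not separate recurrence from height. Of the mock peaks, 85.5% lay at a shared region. The share with a mock peak depends on height: with lists of equal length it was 64.5%.

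Mock-free regions lay at protein-coding genes more often than mock peaks did, but the sets also differed in height. Of the 4920 mock-free regions on the 21 chromosomes, 2636 had their summit in a gene body or within 2000 bp of one (53.6%, Wilson 52.2 to 55%). Random placement gave 5.55%, a 9.66-fold difference (permutation p = 0.000999). Displacement by 10 to 100 kb gave a higher base, 8.25% for these regions and 8.45% for mock peaks. Among mock peaks the share was 15.8% of 973, itself 2.85 times the random share (permutation p = 0.000999), and among shared regions with a mock peak it was 12.2% of 744. Among the 646 mock-free regions tall enough for a 0.95 chance of a call at the mock's depth, it was 13.2% (Wilson 10.8 to 16%). Among all 2287 shared regions of this chance, unplaced ones included, 1200 held a mock peak (52.5%), where 2278 calls were computed. The chance thus overstates what the mock found. Many of the mock-free regions lay at gene edges. Within 500 bp of an edge lay 23.0% of mock-free regions, 16.7 times the random share, and 5.24% of mock peaks, 3.8 times theirs. The excess was not limited to edges. Gene bodies, their edges included, held 40.0% of mock-free regions, 13.0 times the random share, and 9.35% of mock peaks, 3.04 times theirs. From 3500 to 3750 bp inside genes lay 0.894% of mock-free regions, against 0.0343% at random, the largest excess of any such stretch. The stretch before it held 0.813% against 0.0518%, and the one after it 0.447% against 0.0382%. Both replicates gave like gene shares when taken whole, 47.3% for replicate 1 and 48.8% for replicate 2.

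**Figure D2:**
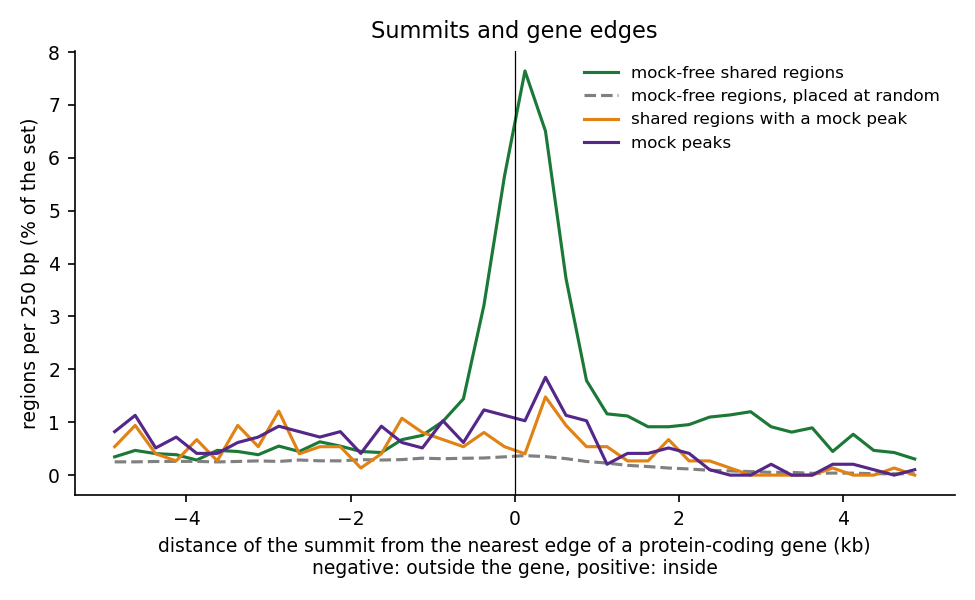
Distance of summits from the nearest edge of a protein-coding gene in kb (negative outside, positive inside) against the share of each set per 250 bp in %, for mock-free shared regions, shared regions with a mock peak, mock peaks and randomly placed mock-free regions (dashed). The mock-free regions peak at the edge, where 23.0% lie within 500 bp, against 5.24% of the mock peaks. Inside genes the mock-free regions stay above random placement at every distance shown.

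The regions at genes were low. Their median was 11 fragments in replicate 1 (quartiles 9 to 14), against 15.5 (10 to 28) for mock-free regions over 2000 bp from genes. The gene share fell from 68.4% of regions with 9 or fewer fragments to 15.2% of the 223 regions with 50 or more. With peaks of −log10 q of at least 5 it was 36.9%, and with lists of equal length 11.4%, both still above random placement (permutation p = 0.000999). The share with lists of equal length was below the 15.8% of mock peaks.

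Mock calls at genes were fewer than computed from depth. Thinned to the mock's depth, the 4861 replicate 1 peaks at genes were computed to give 1784 calls, and 105 lay at a mock peak (2.16%, Wilson 1.79 to 2.61%). For the 5408 peaks over 2000 bp from genes the figures were 3082 and 699 (12.9%). The same computation for replicate 2 gave 3820 calls at genes, and 2742 of the 4861 peaks lay at a replicate 2 peak. It therefore overstates what a second library finds, by a ratio of found to computed of 0.718 at genes in replicate 2, and the ratio in the mock was 0.0589. Among peaks of like chance, those at genes were found more often than others in replicate 2 (Mantel-Haenszel odds ratio 2.24, 95% interval 2.04 to 2.46) and less often in the mock (0.557, 0.438 to 0.708). In the mock the odds ratio was 0.207 (0.131 to 0.325) for peaks under 25 fragments. For peaks of at least 25 it depended on the matching, with 1.01 (0.736 to 1.37) at like chance and 0.599 (0.45 to 0.796) at like numbers of fragments. Among shared regions tall enough for a 0.95 chance of a mock call, 59 of 144 at genes and 521 of 1082 away from genes had a mock peak, which did not pass Fisher's exact test (p = 0.11). The mock is a single library, so this compares libraries and not conditions.

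**Figure D3:**
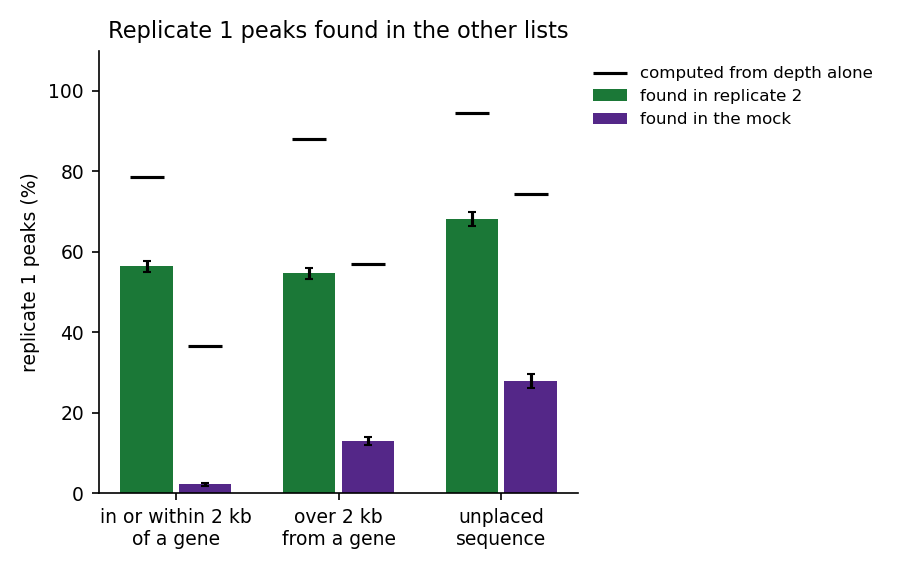
Replicate 1 peaks (%) found in replicate 2 and in the mock, by place, with Wilson 95% intervals as error bars and the share computed from depth alone as a horizontal line. At genes 56.4% were found in replicate 2 and 2.16% in the mock, and on unplaced sequence 68.2% and 28%.

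Target genes numbered 2581, or 2.53% of protein-coding genes on the chromosomes. A single region lay at 2341 of them, 2 regions at 216 and 3 or more at 24. The target gene ranked highest was LOC123069090, with a summit inside the gene at chromosome 1A, 575562708 to 575563167, and a fold of 37.9 in replicate 1 and 31.8 in replicate 2. LOC123123633 followed, with its summit in the gene body on chromosome 5D, 540783467 to 540784062. It had 888 and 789 fragments and folds of 31.6 and 31.3. LOC123139023 on 6B (669801007 to 669802017) had 512 and 480 fragments, and no other mock-free region at a gene had over 159 fragments in replicate 1. On chromosome 1B, 3 of the 20 top genes lay close together. They were LOC123147329 (region 670485399 to 670485803), LOC123147319 (670560499 to 670560989) and LOC123147346 (670571506 to 670571907), with replicate 1 folds of 26, 31.5 and 19.1. The table gives these genes no common name. The 20 top genes had folds from 14.1 to 37.9 in replicate 1 and from 11.2 to 31.8 in replicate 2, against medians of 5.87 and 5.76 over all mock-free regions at genes. Several of these genes had regions of 50 or more fragments in replicate 1. At that height 15.2% of mock-free regions lay at genes. Among mock peaks of any height it was 15.8%, which is not matched for height.

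Of 180 protein-coding genes with a common name or synonym in the table, 6 were targets, named here after their values were seen. LOC543315 (PRO1, a profilin, which binds actin) had folds of 8.21 and 8.1 at a summit in the gene body on 7A, 68245199 to 68245417. LOC123103210 (UBA2, a ubiquitin-activating enzyme) had 8.43 and 6.56 at a summit 161 bp outside the gene on 5A, 330308560 to 330308907. LOC543227 (APT1, an adenine phosphoribosyltransferase) had 6.95 and 5.84 on 5B. LOC542949 (TCTP, the translationally controlled tumour protein) had 6.68 and 5.16 on 4D, 512 bp outside the gene. LOC543074 (TPC1, a cation channel of the vacuole) had 5.6 and 5.59 on 3B, 7078 bp inside the gene. LOC100049018, whose synonym rbcl is the name of the plastid gene for the large subunit of Rubisco, had 4.95 and 5.46 on 2D, with 45 and 39 fragments. The first 5 of these rested on 8 to 15 fragments per replicate.

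The 5 mock-free regions of highest mean percentile rank of fold included none known to lie at a gene. The first, on 7B from 404155263 to 404155434, was 172 bp wide with 1833 and 1481 fragments and folds of 54.9 and 51.7. Next were regions on 4A (397003547 to 397003732, folds 49.1 and 45.5), 1B (679772779 to 679772956, 42 and 41.6), 7D (642910227 to 642910433, 40.1 and 36.7) and unplaced sequence (347032718 to 347032905, 37.3 and 32.1). The 4 placed regions had no protein-coding gene within 2000 bp.

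Bread wheat carries the A, B and D subgenomes. Mock-free regions numbered 1611 on A, 1860 on B and 1449 on D chromosomes, or 32.4, 35.4 and 36.2 per 100 Mb. The D share of 29.5% (Wilson 28.2 to 30.7%) compared with 28.1% of the length, and the 3 shares differed from the length shares (multinomial draws, permutation p = 0.0044). Counted per 1000 protein-coding genes, the order was different, with 48.6 on A, 52.9 on B and 43.0 on D (permutation p = 1e-04 against gene shares, the smallest possible). Mock peaks departed from the length shares too, with 28.2% on A, 40.8% on B and 31.0% on D (permutation p = 1e-04, the smallest possible), so the departure was not particular to mock-free regions. The excess on D over length was small and turned with the choice of regions: the D share was 21.2% with lists of equal length, and replicate 1 alone gave 28.3% with a permutation p of 0.0764.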

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

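The alternatives gave 73 comparisons in which the value or its test could differ from the main one. Of these, 61 kept their direction and side of the threshold, or stayed within 1.5 times the main count. Displacement by 10 to 100 kb can change only the random base and the test, not the value. The alternatives were fixed before the data were examined except the 2 region choices named as later below, and the gene share stands in for the planned promoter share. Overlap of replicate 2 with replicate 1 ranged from 77 to 89.8%, that of replicate 1 with replicate 2 from 50.4 to 86.1%, the share with a mock peak from 11.9 to 64.5% and the gene share from 11.4 to 56.2%, each past the test in every alternative (permutation p = 0.000999). That test is against random placement and does not compare mock-free regions with mock peaks. The lowest gene share, 11.4% with lists of equal length, lay below the 15.8% of mock peaks, so the order of the main setting reversed there. With −log10 q of at least 5, there were 4487 shared regions, 3272 mock-free regions and 909 target genes. With lists of equal length, cut to the length of the mock list, there were 1505, 534 and 31, and the D share reversed to 21.2%. From each replicate alone, mock-free regions numbered 6935 to 11323 and target genes 2944 to 4238, and the D share was 28.3 to 29.4%, with a permutation p of 0.0764 for replicate 1 alone. Later choices, made after seeing the data, were of 2 kinds. Regions with a chance of a mock call of at least 0.95 left 86 target genes, a D share of 25.1% and a gene share of 13.2%. Among mock peaks of any height the gene share was 15.8%. Regions over 10 kb from a plastid-type tRNA or rRNA gene left 2487 target genes and a gene share of 56.2%. Their D share was 28.6%, beside 28.1% of the length (multinomial draws, permutation p = 0.0339). Counts rose with either replicate alone, where a call in both was not required. The cause of the turn of the D share was not tested. Restriction to the 21 chromosomes cannot move the subgenome shares and is not counted. Depth limits the target list: 144 of 2727 shared regions at genes were tall enough for a 0.95 chance of a mock call, and 59 of these had one. No paired analysis was possible because the mock has a single library. The GTAC test with its windows and controls, the gene lists, promoters and genes with upstream regions only were not run, since strand, product names and sequence were not used here.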

Other observations

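All tests in this part were chosen after the results were seen. Mock-free regions also lay near some kinds of non-coding genes. The first 1 Mb of chromosome 1A held 34 of them and 114 rRNA genes, with no protein-coding gene. A window from 86000001 to 87000000 on 1B held 21 and 25 rRNA genes. Within 2000 bp of an rRNA gene lay 80 mock-free regions (1.63%), against 0.776% after displacement by 10 to 100 kb. Long non-coding RNA genes had 4.57% of the regions near them and pseudogenes 4.61%, against 1.65% and 2.2% after the same displacement. Near the 2434 snoRNA genes lay 2 regions (0.0407%), against 0.0254% after displacement. The 871 snRNA genes had 9 regions near them (0.183%), against a mean of 0.0294% and a highest of 0.122% after displacement. Of 973 mock peaks, 0 lay near snRNA genes (Wilson upper end 0.393%), so the mock cannot tell whether it shares this excess. Mock peaks had 3.49%, 3.6% and 5.04% near rRNA, long non-coding RNA and pseudogenes, against 0.935%, 2.33% and 2.56% after displacement. The rRNA and pseudogene excesses were therefore not particular to the mock-free regions. For long non-coding RNA genes the mock share lay within its displaced range, which reached 4.11%. The outer 10% at each chromosome end held 26.0% of mock-free regions, 31.0% of mock peaks and 36.3% of protein-coding genes.

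The mock had fewer peaks than either replicate and a smaller share of them at genes, 15.8%, which was still 2.85 times the random share, while the median height over its own list, 16 fragments, was above the 12 of each replicate. Lower depth alone is argued against: at 806 replicate 1 peaks of at least 50 fragments with a mock peak, the mock had a median of 0.228 of the fragments (bootstrap 95% interval 0.22 to 0.237), beside a ratio of depths of 0.449. That lower height alone made mock peaks rarer at genes than away from them is argued against for replicate 1 peaks under 25 fragments. Among such peaks of like chance the odds ratio of a mock peak at genes was 0.207 (0.131 to 0.325). With the chance computed at the height ratio of 0.228 it was 0.192 (0.122 to 0.303). The odds ratio compares low peaks at genes with low peaks away from them. It cannot tell whether low peaks as a whole were within the mock's reach. For peaks of at least 25 fragments the question stays open, since the odds ratio was 1.01 (0.736 to 1.37) at like chance and 0.599 (0.45 to 0.796) at like numbers of fragments. Antibody-directed signal in and near genes stays open as a hypothesis, and so does tagmentation of open chromatin, which may differ if the mock was prepared in another way than the replicates.

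Regions lay at tRNA genes of a particular kind. Of 136 tRNA genes with a mock-free region within 2000 bp, 131 had an anticodon of the plastid set (96.3%), against 62.5% of all tRNA genes, and in the mock it was 97 of 97. On 5D, from 506484704 to 506622702, a stretch with 18 such genes held 40 peaks in replicate 1, 28 in replicate 2 and 10 in the mock, on a background 13.0, 12.6 and 11.6 times the lowest. This is consistent with reads of plastid DNA placed on nuclear copies of it, and rbcl among the target genes may belong here. Absence of a mock peak did not remove such regions, and the chromatin of the insertions themselves was not tested.

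Of the shared regions, 1446 lay at mock peaks. The narrowest replicate 1 peak was 0.967 of the length that a background step stands for, and the mock list gave 0.971. Scaling a mock control up to the depth of replicate 1 would give 0.436. This is consistent with peaks called on each library without the mock, so that mock signal was still in the replicate lists. Scaling replicate 1 down to the mock was not computed, so this ratio alone cannot exclude a mock control. Calling options are not given in the sources used here.

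Among mock-free regions, 72 had over 100 fragments in replicate 1, and the 5 of highest mean rank of fold were 172 to 207 bp wide.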
